A study of Mus musculus with 12 samples.

How the data were processed

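RNA sequencing counts were examined for 12 samples of the 4T1 line, a mouse model of triple-negative breast cancer that grows in the mammary fat pad of BALB/c mice. Per the labels, 6 samples were cell cultures, with 3 titled as POGZ knockout and 3 as VC, the control, and 6 were tumors with the same 3 and 3. Per the labels' protocols, the cells grew in DMEM with 10% FBS and were lysed at 75% confluency. For the tumors, cells were inoculated into the mammary fat pad of BALB/c mice of 8 weeks, and the tumors were resected at 28 days and flash frozen. RNA was purified on columns, and libraries were made with a KAPA RNA Hyper Prep kit with Ribo-Erase depletion of ribosomal RNA, per the labels' protocols.

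The authors deposited a table of raw counts per gene for the cultures and another for the tumors, each with 39017 Ensembl genes and 1 column per sample. Per the submitters' processing notes, Trimmomatic 0.32, STAR 2.3.0e, featureCounts 1.4.4 and the mm10 genome were used. The notes do not give the settings of these tools, the annotation release or whether reads were counted by strand. Counts of genes that overlap on opposite strands, and of pseudogenes, are therefore less certain than others. The deposited counts were whole numbers and were used without change.

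Counts were analyzed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings, library sizes were scaled by TMM, and the quasi-likelihood test was run with Benjamini-Hochberg adjustment, with a gene called at an adjusted p under 0.05. Cultures and tumors were fitted apart. The difference between the 2 effects was tested as the interaction of label and system over all 12 samples, and a further test compared the 3 control-labelled tumors with the 3 control-labelled cultures. Fold changes are given on the log2 scale with their standard error (SE), taken as the size of the log2 fold change over the square root of the F statistic, and levels as CPM, counts scaled by the total count of the library, with their standard deviation (SD) and n = 3 per group. Genes were named and placed on GRCm38, the same assembly as mm10, by Ensembl ID through GENCODE M21, which held 37607 of the 39017 IDs.

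Before the data were examined, the samples, the tests, 25 pathway lists, 14 cell type lists, the alternatives and the rule for named genes were fixed. The rule took Pogz, 10 genes of the TGF-beta and EMT field in both systems, and the 10 called genes with the largest rise and the 10 with the largest fall. Those had to have a mean log2 CPM of at least 1, groups without overlap and a symbol other than a clone name. It also took the 10 genes with the smallest p of the difference test, up to 4 called members of each list with the smallest p, and up to 2 of the highest mean where no member was called. Other named genes were chosen after their values were seen, as the text says at several of them. The rule did not cover the comparison of control-labelled tumors with cultures, so the choice of genes named there lay outside it. Of the genes of the TGF-beta field, 1 is not reported here, for a reason that does not depend on its values. The lists held 1006 different symbols, of which 1003 matched a gene. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists measured in culture or the 39 measured in tumors. Camera was repeated with the correlation estimated from the data, and fry was run as another test.

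The median log2 fold change of each chromosome was taken over 10525 genes with a mean log2 CPM of at least 3, in whole chromosomes and in windows of 25 genes in order of position. This was chosen after the data were seen. For single libraries, the log2 ratio was taken to the mean of the control-labelled libraries of the same system, without the library itself. A control-labelled library was thus compared with fewer libraries than a knockout-labelled one, which widens the control values. The culture test was repeated with each chromosome's median taken out as an offset. A group with no counts was given a floor of 3 counts per library, which covers counting error alone.

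Alternatives tried 1 at a time were RLE and upper-quartile scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, all 12 samples in 1 fit, an adjusted p of 0.01, a test against a fold change of 1.2 (glmTreat), a block for the culture numbers, and leaving out each library. Alternatives added after the data were seen left out ribosomal and small structural RNA genes, thinned the tumor libraries to the smallest total, left out tumor POGZ_VC_8451 and tumor POGZ_KO_8459, added the Xist level as a covariate, and took out the chromosome medians. Python 3.11.15 with pandas 2.3.3 read the tables and drew the figures.

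Total counts ran from 14724518 to 21863223 in cultures and from 4712001 to 13043831 in tumors. The test was run on simulated counts in which 200 genes were changed 2-fold or 4-fold. Library sizes were real, and each gene had its mean over all libraries of the comparison and its estimated spread. It called 88.4% of the genes changed 2-fold and 100% of those changed 4-fold in the culture simulation of 15521 genes, and 13.7% and 69.5% in the tumor simulation of 16874 genes. In the difference simulation of 17946 genes it called 26.8% and 60.8%, and in the simulation of control-labelled tumors against cultures, with 16815 genes, 55.1% and 93.8%. In both of these simulations cultures and tumors shared the same mean and spread for each gene, unlike the real data, so these shares may not hold there. Unchanged genes called numbered 10 in the culture, 8 in the tumor and 5 in the difference simulation, and 11 for control-labelled tumors against cultures. All these shares were obtained with 200 changed genes and may differ where more genes change.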

Results

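RNA levels were measured by ribosomal-RNA-depleted sequencing in 12 libraries of the 4T1 mammary carcinoma line. There were 3 control-labelled and 3 knockout-labelled cultures, and 3 control-labelled and 3 knockout-labelled tumors grown in BALB/c mice. The title of the series concerns POGZ loss, TGF-beta signaling and metastasis. POGZ is a zinc finger protein that binds heterochromatin protein HP1. The comparisons ask which genes and pathways differ between samples labelled as POGZ knockout and as control. Total counts of the control-labelled cultures 1, 2 and 3 were 17714560, 18643217 and 18509599, and those of the knockout-labelled cultures were 17258582, 14724518 and 21863223. The control-labelled tumors POGZ_VC_8447, POGZ_VC_8448 and POGZ_VC_8451 had 4712001, 8338828 and 7526288 counts, fewer than the 12128993, 13043831 and 12184618 of the knockout-labelled tumors POGZ_KO_8454, POGZ_KO_8455 and POGZ_KO_8459. Nothing in the labels says that the 3 libraries of a culture group are separate cell clones or separate cultures. Every p measures the spread between these samples. An effect of POGZ loss therefore cannot be told apart from other differences between the cell lines that carry the labels. No gene or list below can be credited to POGZ loss alone.

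Pogz RNA was higher, not lower, in the knockout-labelled cultures. Pogz (ENSMUSG00000038902, chromosome 3, 94837567 to 94882326, plus strand, GRCm38) stood at 50.3 ± 2.03 CPM (SD, n = 3) in control-labelled cultures and at 68.3 ± 0.428 CPM (SD, n = 3) in knockout-labelled cultures. Its log2 fold change was 0.45 ± 0.04 (SE; edgeR, Benjamini-Hochberg adjusted p = 3.66e-06), and all 3 knockout-labelled cultures lay above all 3 controls (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 samples can give). The median gene of chromosome 3 was itself 0.33 higher. With that median taken out, chosen after the data were seen, Pogz stood at 0.12 ± 0.04 (edgeR, Benjamini-Hochberg adjusted p = 0.0404). Over all alternatives of the culture value, this one included, the adjusted p ran from 2.93e-14 to 0.098. In tumors the Pogz log2 fold change was 0.11 ± 0.20 (edgeR, Benjamini-Hochberg adjusted p = 0.944; exact permutation test, two-sided p = 0.8). Control-labelled tumors held 99.3 ± 11.9 CPM and knockout-labelled tumors 107 ± 23.4 CPM (SD, n = 3). The tumor log2 fold change was -0.005 without tumor POGZ_VC_8447 and -0.068 without tumor POGZ_KO_8454. Because the RNA of the targeted gene moved against the label in culture, groups are named by their labels throughout, and every direction is that of the knockout-labelled over the control-labelled samples. An edit that shifts the reading frame need not lower the transcript, and the files give neither the edited site nor the protein.

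In culture, camera at the preset correlation placed the lists of TGF-beta target, interferon and cholesterol synthesis genes higher and those of hypoxia, ATF4 and DNA replication genes lower in knockout-labelled cells. With an estimated correlation 0 lists passed, and these 6 had adjusted p from 0.0525 to 0.075. By fry 21 lists passed, 8 higher and 13 lower. These 6 were among them (fry, Benjamini-Hochberg adjusted p from 9.32e-06 to 3.18e-05), and so were some lists that camera did not call, such as Notch and Hippo targets (0.00158). Ccn2, connective tissue growth factor, rose from 110 ± 7.25 to 435 ± 12.8 CPM (SD, n = 3), and Fn1, fibronectin, rose from 772 ± 34.5 to 1877 ± 49.0 CPM. Rsad2, an antiviral interferon-induced gene, rose from 12.1 ± 0.910 to 36.4 ± 1.70 CPM, while Car9, a carbonic anhydrase induced by hypoxia, fell from 27.2 ± 2.87 to 4.48 ± 0.419 CPM. edgeR called 7523 of 15705 genes at a Benjamini-Hochberg adjusted p under 0.05, with 3610 higher and 3913 lower. Of these, 764 changed over 2-fold, 300 up and 464 down, and 228 changed over 4-fold, 65 up and 163 down. The groups did not overlap for 4178 genes that were higher and 4558 that were lower, 55.6% of those tested, where chance gives 10%. All 12 samples in 1 fit, which gives the cultures the wider spread of the tumors, called 1501 genes. The test against a fold change of 1.2 called 3085.

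The largest rises in culture included Bst1, an ectoenzyme that makes cyclic ADP-ribose, and Apob, the apolipoprotein of low-density lipoprotein. Bst1 rose by a log2 fold change of 3.97 ± 0.05 to 145 ± 5.26 CPM (SD, n = 3) and Apob by 3.47 ± 0.10 to 32.6 ± 1.91 CPM (edgeR, Benjamini-Hochberg adjusted p = 1.02e-13 and 1.01e-10). The other 8 largest rises, from 2.84 to 4.25 on the log2 scale, were those of Kctd12b, Ubqln2, Ifi44, Acpp, Fam43a, Cers3, Cyp2c55 and Pet2. Among the largest falls, Sema3c, a secreted semaphorin, fell from 124 ± 1.57 to 2.22 ± 0.203 CPM and Marcks, an actin-binding substrate of protein kinase C, from 76.3 ± 1.64 to 1.83 ± 0.519 CPM. Their log2 fold changes were -5.80 ± 0.06 and -5.32 ± 0.10 (edgeR, Benjamini-Hochberg adjusted p = 2.27e-14 and 5.14e-12). Slc17a2 had no count in the knockout-labelled cultures, at least 26.4-fold lower than the 4.54 CPM of the controls against a floor of 3 counts per library. Dmd, Pof1b, Sema6a, Serpine2, Armcx4, Zfhx4 and Ctse also fell, from means between 4.99 and 17.6 CPM in the control-labelled cultures to means between 0.0651 and 0.374 CPM.

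**Figure D1:**
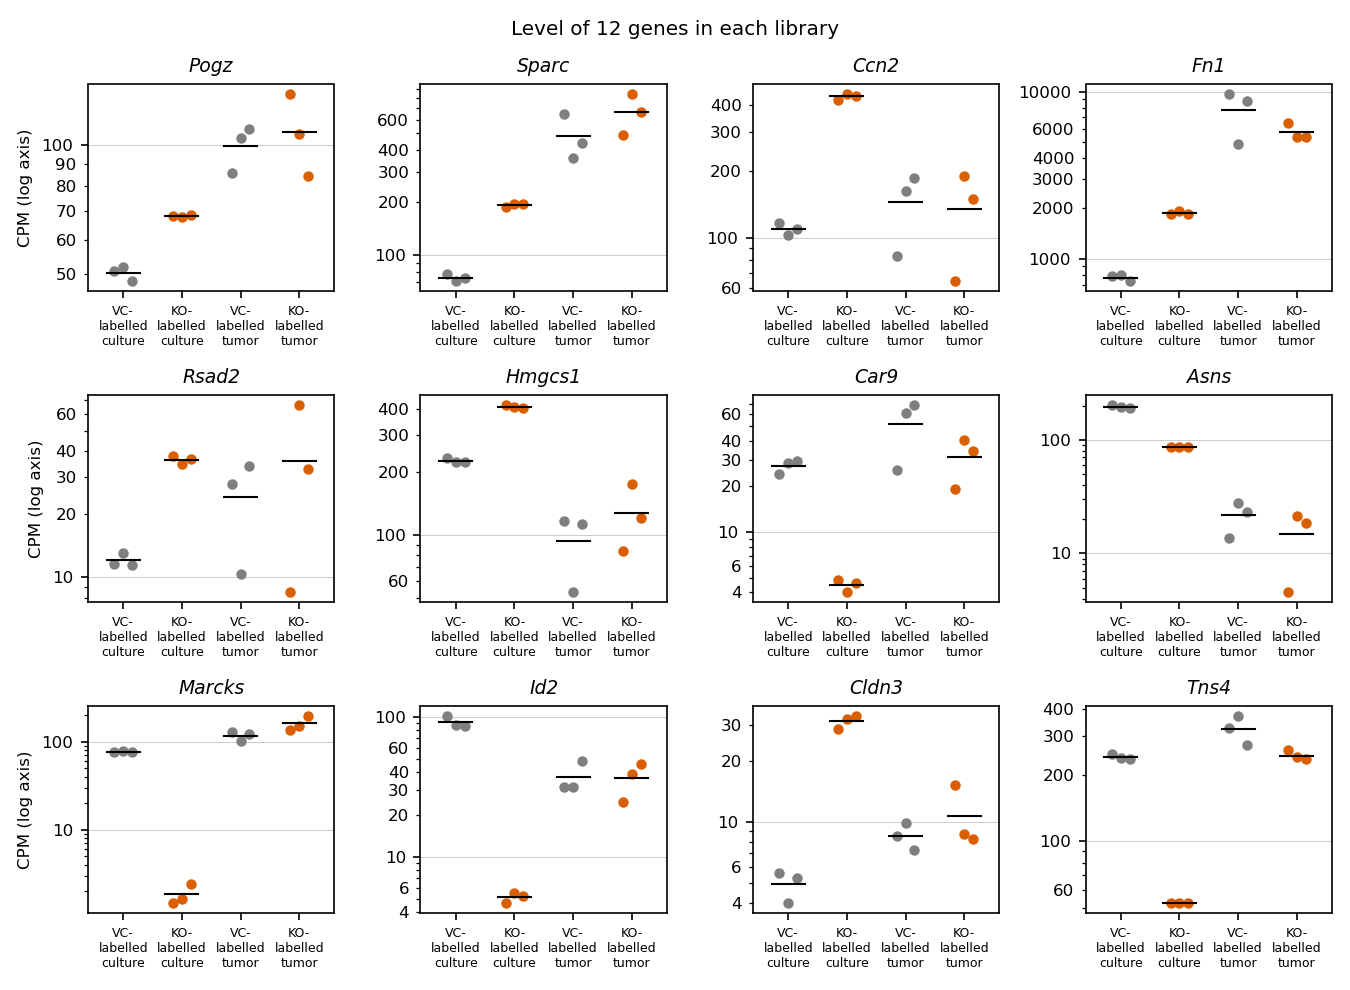
Level of 12 genes in CPM (logarithmic vertical axis) in each of the 12 libraries, with 1 point per library and a line at the mean of the 3 libraries of a group (VC, control; KO, knockout). Sparc, Ccn2, Fn1, Rsad2, Hmgcs1 and Cldn3 stood higher and Car9, Asns, Marcks, Id2 and Tns4 lower in all 3 knockout-labelled cultures, while the 2 groups of tumors lay closer together for Marcks and Id2.

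Among TGF-beta target genes, 16 of 31 measured members rose and 8 fell in culture, with the same counts adjusted over the list alone. Ccn2 rose by 1.99 ± 0.05 on the log2 scale, Nuak1 by 1.14 ± 0.04 and Itgb6, an integrin subunit that helps activate latent TGF-beta, by 1.10 ± 0.04. Camera placed the list higher (Benjamini-Hochberg adjusted p = 1.72e-07; adjusted p = 0.0525 with an estimated correlation). Smad7, the inhibitory SMAD that TGF-beta induces, had a log2 fold change of 0.05 ± 0.05. The ligands and receptors went both ways, since Tgfb2 (0.39 ± 0.07) and Tgfb3 (0.28 ± 0.07) rose while Tgfb1 (-0.40 ± 0.07) and Tgfbr1 (-0.42 ± 0.06) fell. Tgfbr2 stood at 0.10 ± 0.04 (edgeR, Benjamini-Hochberg adjusted p = 0.0382), and its call was lost without control-labelled culture 2 or 3 or without any 1 of the knockout-labelled cultures, with adjusted p from 0.0596 to 0.108. Of 25 TGF-beta ligands, receptors and SMADs measured, 10 rose and 9 fell (11 and 9 adjusted over the list alone), among them Inhbb up by 1.84 ± 0.28, Eng up by 0.61 ± 0.05 and Bmp7 at -0.91 ± 0.09 (camera, Benjamini-Hochberg adjusted p = 0.853).

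The BMP and ID genes split. Id2, a helix-loop-helix inhibitor of differentiation, fell from 91.6 ± 8.70 to 5.13 ± 0.447 CPM (SD, n = 3; log2 fold change -4.15 ± 0.09), and Id4 fell from 0.762 ± 0.233 to 0.0732 ± 0.0901 CPM, while Id1 and Id3 rose by 0.68 ± 0.09 and 0.98 ± 0.09 on the log2 scale. In all, 3 of 6 members rose and 2 fell, also adjusted over the list alone, with a median of 0.19 against a mean of -0.62 and a test direction that was down (camera, Benjamini-Hochberg adjusted p = 0.163). Without control-labelled culture 1 the BMP and ID genes passed the camera threshold at the preset correlation (adjusted p = 0.0204). With an estimated correlation over all cultures, camera gave an adjusted p = 0.609. Of 17 mesenchymal and EMT genes, 8 rose and 4 fell, also adjusted over the list alone, and camera placed the list higher (Benjamini-Hochberg adjusted p = 0.00942; adjusted p = 0.609 with an estimated correlation). Sparc, a secreted matrix protein, rose from 73.9 ± 3.81 to 193 ± 3.46 CPM (SD, n = 3) and Fn1 by 1.29 ± 0.05 on the log2 scale, while Twist1, a transcription factor of EMT, and the receptor kinase Axl changed by -1.43 ± 0.10 and -0.52 ± 0.04. Vim, vimentin, stood at -0.19 ± 0.05, a call lost without knockout-labelled culture 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0575). Cdh1, E-cadherin, stood at -0.20 ± 0.05, a call lost without knockout-labelled culture 3 (edgeR, Benjamini-Hochberg adjusted p = 0.0582). Epithelial genes went both ways, with 12 of 31 up and 14 down, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.989). Cldn3, a tight junction claudin, rose by 2.68 ± 0.11, and Krt14, a basal keratin, and Tjp3, a tight junction scaffold, changed by -1.61 ± 0.11 and -1.08 ± 0.05. Collagens and matrix glycoproteins (8 up and 9 down of 18) and matrix proteases and inhibitors (6 up and 9 down of 22; 7 and 9 adjusted over the list alone) did not pass camera (Benjamini-Hochberg adjusted p = 0.853 and 0.553).

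The type I interferon response rose, with 29 of 33 members higher and 1 lower by the test and 30 and 1 adjusted over the list alone. Ifi44 rose by 3.21 ± 0.18, Ifit3 by 2.56 ± 0.15, Rsad2 by 1.60 ± 0.07 and Parp14 by 0.71 ± 0.04 on the log2 scale (camera for the list, Benjamini-Hochberg adjusted p = 1e-15; adjusted p = 0.0525 with an estimated correlation). Antigen presentation by MHC class I had 7 of 20 members up and 2 down, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.602). NF-kB and inflammatory cytokines went both ways, with 10 of 28 up and 11 down, or 11 and 13 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.853). In that list Csf1, the growth factor of macrophages, and Ccl2, a monocyte chemokine, rose by 1.24 ± 0.04 and 1.42 ± 0.08, and Nos2, the inducible nitric oxide synthase, and Il1a changed by -2.11 ± 0.10 and -0.87 ± 0.04. Of 5 measured genes of the list for dendritic cells and MHC class II, Bst1 rose and Batf3 fell, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.08e-05; adjusted p = 0.0543 with an estimated correlation). The median of those 5 was 0.09 and the mean 0.52. Batf3, at -1.40 ± 0.41 (edgeR, Benjamini-Hochberg adjusted p = 0.0128), lost its call without control-labelled culture 3 or knockout-labelled culture 1 or 3 (adjusted p from 0.0553 to 0.0662).

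Cholesterol and SREBP targets rose together, with 24 of 32 up and 2 down, or 26 and 2 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.39e-10; adjusted p = 0.0543 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, rose from 227 ± 5.79 to 412 ± 7.18 CPM (SD, n = 3), and Idi1, Pmvk and Lss rose by 0.98 ± 0.07, 0.87 ± 0.06 and 0.75 ± 0.04 on the log2 scale. Hypoxia and glycolysis genes fell, with 3 of 34 up and 24 down, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.04e-08; adjusted p = 0.0525 with an estimated correlation). Examples were Car9 at -2.59 ± 0.11, the oxygen sensor Egln3 at -1.01 ± 0.06 and the glycolytic enzymes Hk2 at -0.91 ± 0.04 and Tpi1 at -0.87 ± 0.04. ATF4 and unfolded protein response genes fell in 22 of 32 and rose in 3, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 4.01e-09; adjusted p = 0.0543 with an estimated correlation). Slc7a11, the cystine transporter, stood at -1.33 ± 0.07, Mthfd2 at -1.19 ± 0.04, Asns, asparagine synthetase, at -1.17 ± 0.04 and the chaperone Pdia4 at -0.79 ± 0.05. Asns, Mthfd2, Pdia4, Hk2 and Tpi1 lie on chromosome 6, where the median gene was -0.45. Oxidative phosphorylation (4 up and 14 down of 36; 5 and 14 adjusted over the list alone), MYC targets and nucleolus (4 up and 13 down of 32; 4 and 14) and cytosolic ribosomal proteins (6 up and 10 down of 38; 5 and 9) did not pass camera (Benjamini-Hochberg adjusted p = 0.258, 0.163 and 0.862).

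DNA replication and E2F targets fell in 26 of 40 and rose in 4, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00223; adjusted p = 0.075 with an estimated correlation). The helicase subunits Mcm3, Mcm2 and Mcm6 stood at -0.90 ± 0.04, -0.57 ± 0.04 and -0.40 ± 0.04, and the licensing factor Cdt1 at -0.44 ± 0.04. The mitosis and G2/M list had 18 of 34 down and 7 up, or 19 and 8 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0366; adjusted p = 0.785 with an estimated correlation). Its call was lost without control-labelled culture 1 (adjusted p = 0.0936) and without knockout-labelled culture 2 or 3 (0.0632 and 0.0536). Foxm1, a transcription factor of mitotic genes, stood at -0.79 ± 0.04, Cdc20 at -0.59 ± 0.05, Cdca8 at -0.51 ± 0.04 and Aurkb at -0.46 ± 0.05. Mcm2 and Foxm1 lie on chromosome 6, Cdc20 and Cdca8 on chromosome 4, and Mcm3 and Mcm6 on chromosome 1. The median genes of these chromosomes stood at -0.45, -0.28 and -0.12. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, stood at -1.59 ± 0.13, and p53 targets as a list had 8 of 23 up and 5 down (9 and 6 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.602). Homologous recombination and Fanconi repair (5 up and 18 down of 36; 6 and 19 adjusted over the list alone) and replication-dependent histones (1 up and 10 down of 26; 1 and 9) did not pass camera (Benjamini-Hochberg adjusted p = 0.186 and 0.109). Replication-dependent histones did pass camera at the preset correlation without knockout-labelled culture 3 (adjusted p = 0.00572), and with the culture numbers as a block (0.0197). With an estimated correlation over all cultures, camera gave this list an adjusted p = 0.939.

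Heterochromatin proteins and POGZ partners had 5 of 32 up and 11 down (5 and 13 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.989), with Mga and Dnmt3a up by 0.81 ± 0.04 and 0.78 ± 0.04 and Trim28 at -0.31 ± 0.04. Of the MAX/MGA-E2F6 repressed germline genes, 5 of the 32 could be measured in culture, where 2 fell and 0 rose by edgeR with 2 at an unadjusted p under 0.05 (camera, Benjamini-Hochberg adjusted p = 0.862). WNT and beta-catenin targets (5 up and 7 down of 15; 6 and 7 adjusted over the list alone) and Notch and Hippo targets (10 up and 6 down of 22; 11 and 6) did not pass camera (Benjamini-Hochberg adjusted p = 0.258 and 0.553). Markers of other cell types were scarce in culture, with 2 to 8 members measured per list, and none of those lists but the dendritic cell list passed camera. The adjusted p was 0.989 for T and NK cells, 0.553 for macrophages and monocytes, 0.931 for neutrophils, 0.989 for fibroblasts, 0.853 for endothelial cells and 0.989 for pericytes and smooth muscle. It was 0.967 for adipocytes, 0.853 for skeletal muscle, 0.989 for mammary luminal and milk genes, 0.122 for skin keratinocytes and 0.989 for erythroid cells (camera, Benjamini-Hochberg).

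**Figure D2:**
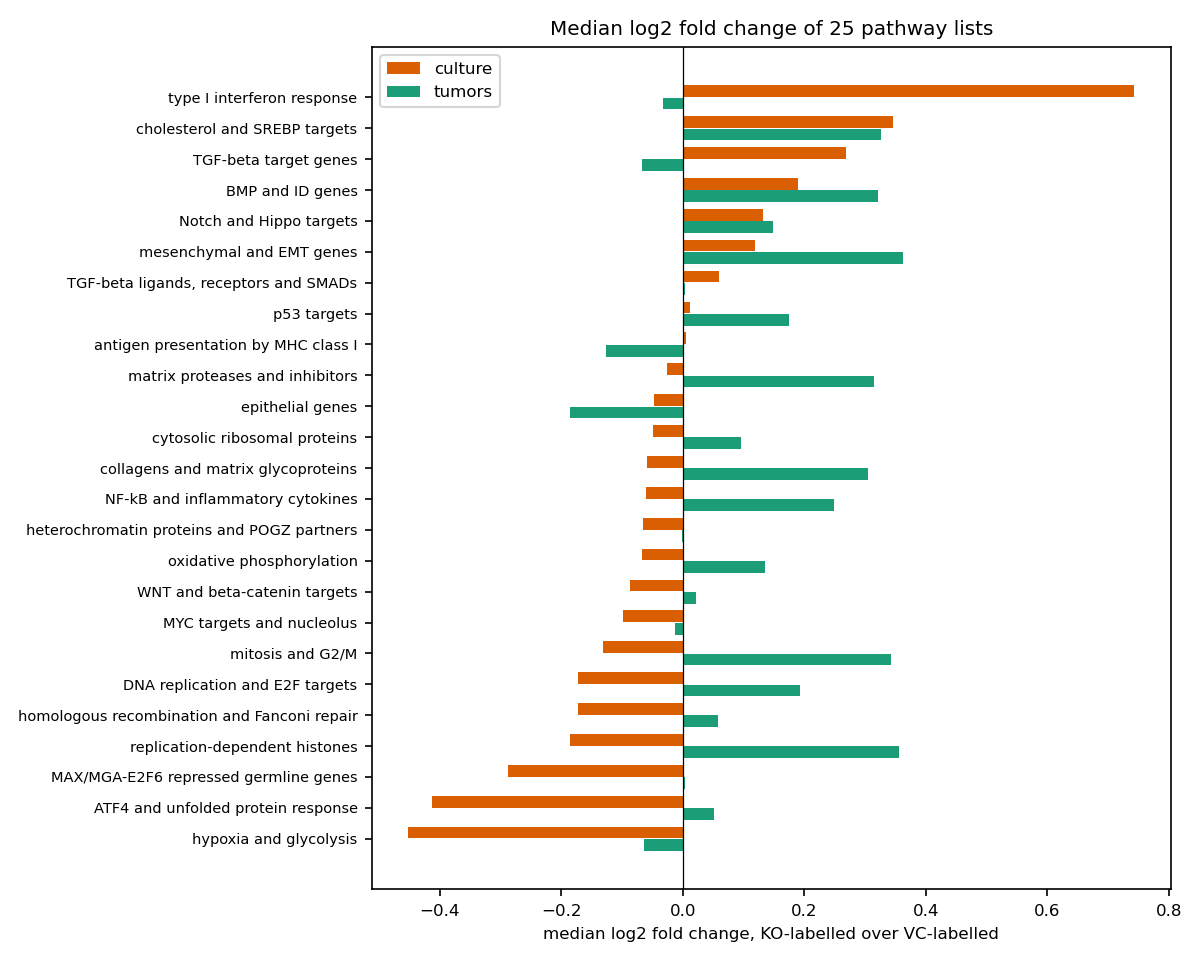
Median log2 fold change, knockout-labelled over control-labelled, of the measured members of 25 pathway lists in culture (orange bars) and in tumors (green bars). The interferon list had the highest median in culture, 0.74, against -0.03 in tumors, and the hypoxia list the lowest, -0.45, against -0.06 in tumors.

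Whole chromosomes or parts of them also differed between the cultures, which was seen and measured after the data were examined. The median gene of chromosome 6 stood at -0.45 on the log2 scale, with 92.7% of 491 genes lower, and the median gene of chromosome 3 at 0.33, with 89.4% of 509 genes higher. Chromosome 4 stood at -0.28, chromosome 2 at 0.25, chromosome 16 at 0.15, chromosome 10 at 0.14 and chromosome 1 at -0.12. All 20 windows of 25 genes along chromosome 6 were lower (-0.56 to -0.28), and all 21 windows along chromosome 3 (0.16 to 0.44), all 36 along chromosome 2 (0.05 to 0.36) and all 14 along chromosome 16 (0.06 to 0.28) were higher. Other shifts covered parts of a chromosome, with 25 of 29 windows of chromosome 4 lower (-0.45 to 0.07), 16 of 21 of chromosome 10 higher (-0.15 to 0.36) and 16 of 25 of chromosome 1 lower (-0.55 to 0.13). Windows 18 to 21 of chromosome 5 stood at 0.31 to 0.53, and windows 1 and 2 of chromosome 13 at 0.49 and 0.37. The medians of these 2 whole chromosomes were 0.10 and 0.00064. The 3 knockout-labelled cultures were alike, with -0.45, -0.46 and -0.46 for chromosome 6 and 0.33, 0.32 and 0.31 for chromosome 3, and the control-labelled cultures lay between -0.01 and 0.01 for both. Tumors had -0.06 for chromosome 6 and 0.12 for chromosome 3.

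With the chromosome medians taken out, which does not remove shifts of parts of a chromosome, edgeR called 6307 genes in culture, 3088 higher and 3219 lower, of which 5266 were among the 7523 and 5147 of those had the same direction. The count of 9 lists also stayed at 9, but without mesenchymal and EMT genes (camera, Benjamini-Hochberg adjusted p = 0.0788) and with replication-dependent histones (adjusted p = 0.00981, and 0.826 with an estimated correlation). TGF-beta targets, interferon, cholesterol, hypoxia, ATF4 and dendritic cell genes then passed camera also with an estimated correlation (Benjamini-Hochberg adjusted p = 0.0429 for each), and so did DNA replication genes (0.0499), while the mitosis list did not (0.580). The dendritic cell list, placed higher, had a median of -0.16, with Bst1 up and 1 of its 5 genes down. On chromosome 6, Asns moved from -1.17 to -0.72, Mthfd2 from -1.19 to -0.74, Hk2 from -0.91 to -0.45, Tpi1 from -0.87 to -0.42, Mcm2 from -0.57 to -0.12, Foxm1 from -0.79 to -0.34 and Pdia4 from -0.79 to -0.33. Cdc20 and Cdca8 on chromosome 4 moved from -0.59 to -0.31 and from -0.51 to -0.23. Mcm3 and Mcm6 on chromosome 1 moved from -0.90 to -0.78 and from -0.40 to -0.28. Cdt1 on chromosome 8 and Aurkb on chromosome 11 moved less, from -0.44 to -0.35 and from -0.46 to -0.42. Ccn2 and Fn1 stood at 1.85 ± 0.05 and 1.41 ± 0.05. Tgfbr1 on chromosome 4 went to -0.15 ± 0.06, Tgfbr2 to 0.07 ± 0.04 and Cdh1 to -0.10 ± 0.05, and these calls ended (edgeR, Benjamini-Hochberg adjusted p = 0.0562, 0.152 and 0.133).

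**Figure D3:**
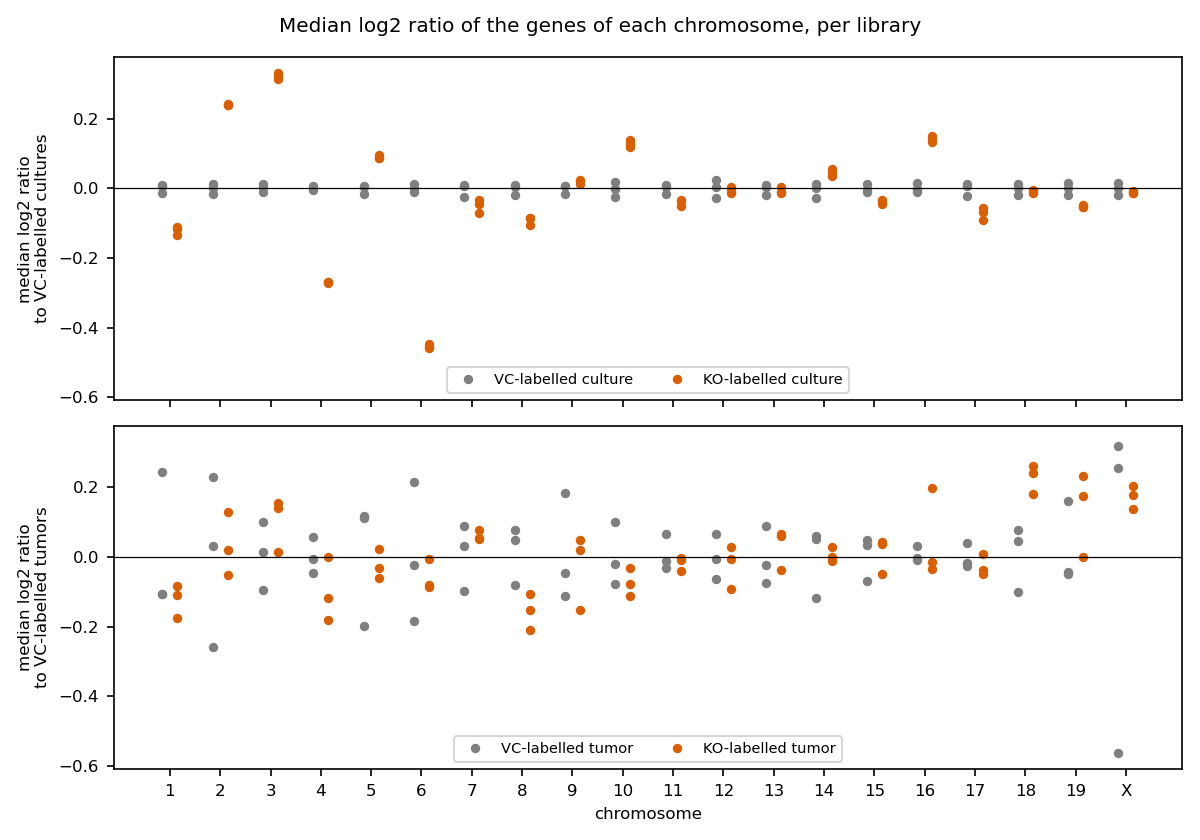
Median log2 ratio of each library to the mean of the control-labelled libraries, over the genes of each chromosome (horizontal axis), for cultures (upper panel) and tumors (lower panel), with 1 point per library (VC, control; KO, knockout). That mean left out the library itself, so each control was set against fewer libraries, which widens its spread. The 3 knockout-labelled cultures lie together, near -0.45 for chromosome 6 and 0.33 for chromosome 3, while the tumors scatter.

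In tumors edgeR called no gene, and camera placed the lists of fibroblasts and milk genes higher in the knockout-labelled group at the preset correlation, but 0 lists with an estimated correlation (adjusted p = 0.725 for both) or with fry. Col3a1, a fibrillar collagen, stood at 942 ± 268 CPM in control-labelled and 1715 ± 695 CPM in knockout-labelled tumors (SD, n = 3), and Col1a1 at 1170 ± 263 and 1742 ± 483 CPM. Csn2, the milk protein beta-casein, was at 2.33, 0.240 and 0.133 CPM in tumors POGZ_VC_8447, POGZ_VC_8448 and POGZ_VC_8451 and at 11.1, 32.4 and 230 CPM in tumors POGZ_KO_8454, POGZ_KO_8455 and POGZ_KO_8459. Of 17153 genes tested, edgeR called 0, with 956 at an unadjusted p under 0.05 where chance gives 858, and the smallest Benjamini-Hochberg adjusted p was 0.344. limma-voom called 0 and DESeq2 called 66, with 26 higher and 40 lower. All 12 samples in 1 fit, which gives the tumors a spread shared with the less variable cultures, called 64, with 16 higher and 48 lower. The groups did not overlap for 879 genes that were higher and 917 that were lower, 10.5% of those tested, where chance gives 10%. The spread between tumors was wide, with a biological coefficient of variation of 28.6% against 5.23% in cultures.

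Some genes chosen after their values were seen, from those that DESeq2 called, had groups that did not overlap. S100a4, a calcium-binding protein of motile cells, was at 84.3, 77.7 and 82.8 CPM in the control-labelled tumors and at 280, 312 and 180 CPM in the knockout-labelled tumors (log2 fold change 1.66 ± 0.21; edgeR, Benjamini-Hochberg adjusted p = 0.509). Prelp, a matrix proteoglycan, stood at 1.95 ± 0.21 (edgeR, Benjamini-Hochberg adjusted p = 0.344), Gsto1 at 1.65 ± 0.28, Gad2 at -2.64 ± 0.40 and Elf3, an epithelial transcription factor, at -1.69 ± 0.35 (edgeR, Benjamini-Hochberg adjusted p = 0.647, 0.647 and 0.693). Spp1, osteopontin, was at 1043 ± 197 and 2067 ± 146 CPM (SD, n = 3; log2 fold change 0.99 ± 0.18; edgeR, Benjamini-Hochberg adjusted p = 0.647). In the TGF-beta field Ccn2 stood at -0.11 ± 0.43, Smad7 at 0.19 ± 0.22, Tgfb1 at 0.17 ± 0.15, Tgfb2 at 0.16 ± 0.27, Tgfb3 at -0.29 ± 0.49, Tgfbr1 at 0.13 ± 0.21 and Tgfbr2 at 0.43 ± 0.19. Vim stood at 0.24 ± 0.19, Cdh1 at -0.18 ± 0.23 and Fn1 at -0.44 ± 0.28. None of these was called by edgeR or DESeq2.

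**Figure D4:**
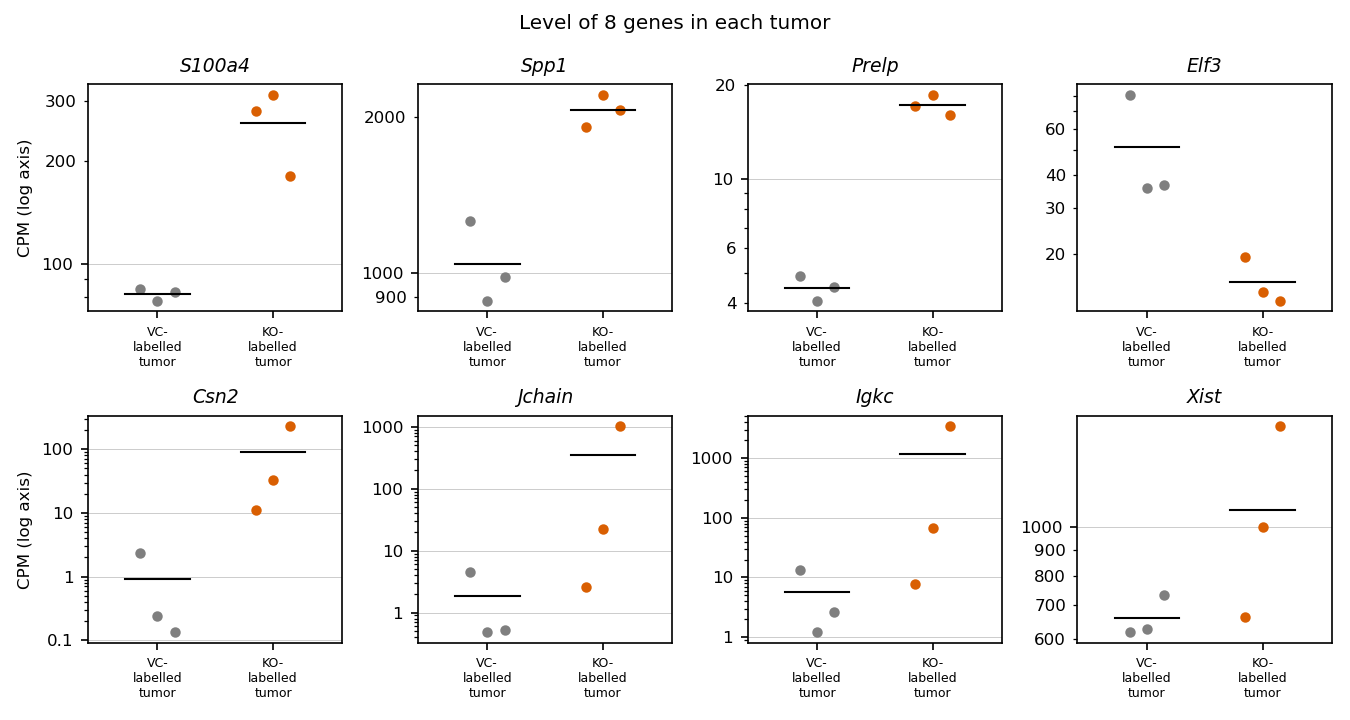
Level of 8 genes in CPM (logarithmic vertical axis) in each tumor, with 1 point per tumor and a line at the mean of 3 (VC, control; KO, knockout). S100a4, Spp1, Prelp and Csn2 stood higher and Elf3 lower in all 3 knockout-labelled tumors, while Igkc and Jchain reached 3423 and 1017 CPM in tumor POGZ_KO_8459.

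Camera at the preset correlation placed 20 of 39 lists past the threshold in tumors, 17 higher and 3 lower, but with an estimated correlation or with fry it placed 0. When the 6 tumors were split with their labels mixed, a median of 17 lists passed at the preset correlation. The calls of fibroblasts (median 0.47, 20 of 20 members higher; 2 up and 0 down adjusted over the list alone), endothelial cells (0.41, 17 of 20), mammary luminal and milk genes (2.304, 9 of 10; 4 up and 0 down adjusted over the list alone) and B and plasma cells (4.09, 8 of 8; 4 up and 0 down adjusted over the list alone) held with each of the 6 tumors left out. Their Benjamini-Hochberg adjusted p were 7.5e-08, 5.1e-05, 7.17e-09 and 1.29e-05 (adjusted p = 0.725 with an estimated correlation for each). The B and plasma cell values came mainly from tumor POGZ_KO_8459, with Jchain, the joining chain of secreted antibodies, at 2.64, 22.2 and 1017 CPM in tumors POGZ_KO_8454, POGZ_KO_8455 and POGZ_KO_8459. Xist, the RNA of the inactive X chromosome of female cells, was chosen after the data were seen. It was at most 0.985 CPM in the cultures. It was at 617, 626 and 732 CPM in control-labelled tumors and at 662, 1002 and 1592 CPM in tumors POGZ_KO_8454, POGZ_KO_8455 and POGZ_KO_8459 (exact permutation test, two-sided p = 0.2). With the Xist level as a covariate 13 lists passed, 6 higher and 7 lower. Fibroblasts, endothelial cells and milk genes were among those higher, B and plasma cells did not pass (adjusted p = 0.761), and mitosis and G2/M was placed lower (adjusted p = 0.0281). Without tumor POGZ_VC_8451 and tumor POGZ_KO_8459, 13 lists passed, 10 higher and 3 lower.

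Other lists that passed in tumors rested on single animals. Mesenchymal and EMT genes (median 0.36, 18 of 25 members higher, 1 up and 0 down adjusted over the list alone), collagens and matrix glycoproteins (0.31, 24 of 29) and matrix proteases and inhibitors (0.32, 20 of 26) were past the camera threshold (Benjamini-Hochberg adjusted p = 4.63e-04, 2.98e-04 and 0.00324; adjusted p = 0.725 with an estimated correlation). Without tumor POGZ_KO_8455 all 3 calls were lost (adjusted p = 0.188, 0.484 and 0.340). The epithelial genes (-0.19, 25 of 32 members lower, 0 up and 2 down adjusted over the list alone), with Lama5 at -0.44 ± 0.22, were placed lower (adjusted p = 1.36e-04; adjusted p = 0.725 with an estimated correlation), a call lost without tumor POGZ_VC_8448 (adjusted p = 0.0952). Without that tumor 13 lists passed, and the calls of mitosis and G2/M (0.34, 33 of 34 members higher, adjusted p = 3.56e-04), replication-dependent histones (0.36, 26 of 26, 9.05e-05), oxidative phosphorylation (0.14, 30 of 36, 0.0111) and cholesterol and SREBP targets (0.33, 30 of 32, 1.14e-04) were also lost (adjusted p = 0.784, 0.188, 0.454 and 0.421). Those 4 lists had adjusted p = 0.818, 0.725, 0.725 and 0.725 with an estimated correlation. With the Xist level as a covariate mitosis and G2/M turned from higher to lower. The calls of mitosis and G2/M and of oxidative phosphorylation were lost without tumor POGZ_KO_8459 too (adjusted p = 0.479 and 0.104), and that of cholesterol and SREBP targets without tumor POGZ_KO_8455 (0.0860). Antigen presentation by MHC class I (-0.13, 16 of 20 members lower; adjusted p = 0.00144) lost its call without tumor POGZ_KO_8454 (adjusted p = 0.370; adjusted p = 0.725 with an estimated correlation).

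The hypoxia and glycolysis list (median -0.06; camera, Benjamini-Hochberg adjusted p = 0.0441; adjusted p = 0.837 with an estimated correlation) lost its call without tumor POGZ_VC_8448, POGZ_VC_8451, POGZ_KO_8454 or POGZ_KO_8459 (adjusted p = 0.686, 0.222, 0.839 and 0.0629). NF-kB and inflammatory cytokines (0.25, adjusted p = 0.0334; adjusted p = 0.758 with an estimated correlation) lost theirs without tumor POGZ_VC_8447, POGZ_VC_8448, POGZ_KO_8455 or POGZ_KO_8459 (0.225, 0.167, 0.846 and 0.104). T and NK cells (0.61, adjusted p = 3.56e-04) and macrophages and monocytes (0.33, 1 up and 0 down adjusted over the list alone, adjusted p = 0.00306) lost theirs without tumor POGZ_VC_8448 (0.188 and 0.551) or tumor POGZ_KO_8459 (0.670 and 0.749). Adipocytes (1.16, 12 of 12 members higher, with Fabp4 at 1.28 ± 0.70; adjusted p = 0.00144) lost theirs without tumor POGZ_VC_8451 (0.398). Pericytes and smooth muscle (0.51, adjusted p = 0.0272) lost theirs without tumor POGZ_VC_8448, POGZ_KO_8455 or POGZ_KO_8459 (0.267, 0.137 and 0.127), and mast cells and basophils (0.98, adjusted p = 0.0285) without tumor POGZ_VC_8447, POGZ_KO_8455 or POGZ_KO_8459 (0.122, 0.121 and 0.536). These 5 cell type lists had an adjusted p = 0.725 with an estimated correlation.

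TGF-beta target genes did not pass in tumors (median -0.07, 14 of 33 members higher; camera, Benjamini-Hochberg adjusted p = 0.328), although without tumor POGZ_KO_8455 they were placed lower (adjusted p = 0.00744). The type I interferon response (-0.03, 15 of 34 members higher, adjusted p = 0.602) had no stable direction. It was placed higher without tumor POGZ_VC_8447 or tumor POGZ_KO_8454 (adjusted p = 0.0403 and 0.0272), and lower without tumor POGZ_VC_8448, POGZ_KO_8455 or POGZ_KO_8459 (1.41e-04, 0.0227 and 0.0356). Further lists that did not pass were TGF-beta ligands, receptors and SMADs (adjusted p = 0.924), BMP and ID genes (0.225), DNA replication and E2F targets (0.0926), homologous recombination and Fanconi repair (0.704) and heterochromatin proteins and POGZ partners (0.625). The same held for MAX/MGA-E2F6 repressed germline genes (0.246; 0 up and 1 down adjusted over the list alone), p53 targets (0.109), ATF4 and unfolded protein response (0.590), cytosolic ribosomal proteins (0.582), MYC targets and nucleolus (0.668), WNT and beta-catenin targets (0.798) and Notch and Hippo targets (0.666). Among cell types, neutrophils (0.355), dendritic cells and MHC class II (0.0973), skeletal muscle (0.968), skin keratinocytes (0.968) and erythroid cells (0.278) did not pass.

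As a set, the genes with large changes in culture showed no like change in the tumors, though some did not differ by the test. Marcks, at -5.32 ± 0.10 in culture, stood at 0.46 ± 0.18 in tumors, and Id2, at -4.15 ± 0.09 in culture, at -0.02 ± 0.28. The gap between the 2 effects was 5.81 ± 0.27 for Marcks and 4.13 ± 0.33 for Id2 (edgeR, Benjamini-Hochberg adjusted p = 1.38e-06 and 1.06e-04). The focal adhesion protein Tns4 stood at -2.20 ± 0.04 in culture and -0.40 ± 0.16 in tumors, and Hsd17b11, a lipid droplet dehydrogenase, went from 0.0367 ± 0.0318 to 3.52 ± 0.717 CPM (SD, n = 3) in culture and stood at 0.43 ± 0.26 in tumors. Cyp2c55 and Acpp, which rose by 2.85 and 3.18 in culture, had differences of -0.49 and -1.62 that were not called (edgeR, Benjamini-Hochberg adjusted p = 0.857 and 0.392). Gramd1b, Armcx4, Zfhx4, Lcp1 and Csgalnact1 fell in culture and had larger log2 fold changes in tumors, with differences from 2.07 to 6.65. Of 18419 genes tested, edgeR called 377 at an adjusted p under 0.05, with the log2 fold change higher for 209 and lower for 168 in tumors relative to culture, and 2831 had an unadjusted p under 0.05. The count was 1588 without tumor POGZ_KO_8454, 629 without tumor POGZ_VC_8448, and 165, 162 and 165 without control-labelled culture 1, 2 or 3, and 153, 155 and 147 without knockout-labelled culture 1, 2 or 3. Over 14873 genes tested in both, the fold changes correlated at 0.07 (Pearson, with a jackknife SE of 0.12 over libraries) and 0.12 (Spearman), across genes that are not independent replicates, and Pearson's value was -0.005 without tumor POGZ_VC_8448 or without tumor POGZ_KO_8454. No gene was called in both systems by edgeR, since 0 were called in tumors, and DESeq2 called 20 in both with the same direction, where independent lists would share 9.49. Tjp3, a tight junction scaffold chosen after its values were seen, was 1 of these, at -1.08 ± 0.05 in culture and -1.63 by DESeq2 in tumors.

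Among the lists, camera on the difference placed the effect of the label on the interferon response lower in tumors than in culture (Benjamini-Hochberg adjusted p = 6.82e-12; adjusted p = 0.975 with an estimated correlation), with 4 of 34 members called lower and 15 adjusted over the list alone. The effect on TGF-beta target genes was also placed lower (Benjamini-Hochberg adjusted p = 0.00626; adjusted p = 0.975 with an estimated correlation), with 4 of 33 members called lower and 7 adjusted over the list alone. The log2 fold changes of Ccn2, of that list, and Fn1, of the mesenchymal and EMT list, were also lower in tumors than in culture, with differences of -2.10 and -1.73. The tumors and cultures were separate libraries with no shared sample, so system, batch and host cells cannot be told apart in this comparison.

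Control-labelled tumors carried more RNA of stromal and macrophage markers than control-labelled cultures, and less RNA of mitosis genes. Macrophage and monocyte markers had mean log2 CPM of -2.113, -1.925 and -1.645 in those cultures and 6.406, 5.647 and 6.086 in those tumors. The mitosis and G2/M list stood at 7.24, 7.2 and 7.158 in the cultures and at 5.615, 4.447 and 5.151 in the tumors. Pecam1, an endothelial adhesion molecule, was at 0.416 ± 0.208 CPM in control-labelled cultures and 66.9 ± 17.2 CPM in control-labelled tumors (SD, n = 3), and Lyz2, a macrophage lysozyme, at 0.0181 ± 0.0314 and 341 ± 201 CPM. Cdh1 changed by -1.38 ± 0.13 on the log2 scale, Mki67, a proliferation marker, by -2.01 ± 0.25 and Pogz by 0.99 ± 0.12 (edgeR, Benjamini-Hochberg adjusted p = 5.08e-05, 2.30e-04 and 1.92e-04). The choice of genes named for this comparison lay outside the fixed rule. edgeR called 11172 of 17123 genes, with 6117 higher and 5055 lower in tumors. Collagens and matrix glycoproteins rose in 21 of 29 (median 6.10), fibroblast markers in 17 of 18 (8.61) and mesenchymal and EMT genes in 22 of 25 (4.50), also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.63e-27, 6.27e-21 and 9.8e-18; adjusted p = 0.015 with an estimated correlation for each). TGF-beta target genes rose in 22 of 31 and fell in 3 (camera, Benjamini-Hochberg adjusted p = 1.6e-05; adjusted p = 0.0433 with an estimated correlation). MYC targets and nucleolus fell in 32 of 32, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.85e-16; adjusted p = 0.0258 with an estimated correlation). Culture and tumor libraries came in separate tables, so a library batch and the system cannot be told apart.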

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

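The tests of the Pogz level, those of the large culture changes and the test of host share for milk and B cell genes were chosen only after the result was seen. The normalizations compared for Pogz and the splits of the samples were fixed before. The tests of depth and lymph node tissue for milk and B cell genes also came after the data were seen. Thinning was added then, and the lymph node test names tumor POGZ_KO_8459.

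The test of the difference between the systems, as the interaction of label and system, called 377 genes, which marks them for a closer look. Relative to culture, the log2 fold change in tumors was higher for Sema3c (7.43), Armcx4 (6.65), Serpine2 (6.62), Sema6a (6.15), Ctse (6.11), Dmd (6.0), Marcks (5.81), Zfhx4 (5.73), Pof1b (5.29), Gramd1b (5.27), Id2 (4.13), Rps6-ps1 (3.71), Lcp1 (2.92), Csgalnact1 (2.07), Tns4 (1.81), Twist1 (1.66), Gsto1 (1.58), Spp1 (0.93) and Axl (0.72). It was lower for Hsd17b11 (-5.84), Apob (-5.75), Kctd12b (-3.78), Gad2 (-3.58), Ubqln2 (-3.34), Ifi44 (-3.30), Bst1 (-2.99), Fam43a (-2.39), Cldn3 (-2.34), Ccn2 (-2.10), Fn1 (-1.73) and Csf1 (-1.40). The values of Serpine2, Hsd17b11, Zfhx4, Dmd, Sema6a, Pof1b, Armcx4, Ctse, Gramd1b, Kctd12b and Fam43a rest on a culture group with low counts, and those of Sema3c, Apob and Pof1b on tumors with low counts, so they depend on the prior count. Rps6-ps1 is a pseudogene, and Gsto1 and Gad2 were chosen after their values were seen.

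Camera on the same difference, at the preset correlation, placed 13 lists past the threshold, and each had a Benjamini-Hochberg adjusted p = 0.975 with an estimated correlation. These are differences in the effect of the label, knockout-labelled over control-labelled, and not in level. The effect was lower in tumors than in culture for the type I interferon response (adjusted p = 6.82e-12), TGF-beta target genes (0.00626), epithelial genes (0.0143) and antigen presentation by MHC class I (0.0202). The effect was higher in tumors than in culture for replication-dependent histones (1.39e-05), oxidative phosphorylation (0.00105), mitosis and G2/M (0.00136), DNA replication and E2F targets (0.00300), hypoxia and glycolysis (0.0170), endothelial cells (0.0343), ATF4 and unfolded protein response (0.0450), macrophages and monocytes (0.0471) and skin keratinocytes (0.0494).

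Genes that changed over 4-fold in culture showed, as a set, no like change in tumors: 177 of the 228 were tested there, 80 of the 177 (45.2%) had the same direction, and the median tumor log2 fold change signed by the culture direction was -0.086 (-0.20 to 0.02 with a tumor left out) against 2.82 in culture, while the difference test called 114 of the 224 it covered (50.9%). Of all 7302 genes called in culture and tested in tumors, at any fold, 57.9% had the same direction. That share was 52.2% without tumor POGZ_VC_8448 and 61.4% without tumor POGZ_KO_8459. The spread and depth of the tumor libraries, which would leave the median near that of culture, are argued against by that median, -0.086. Dilution of tumor cells by host RNA is argued against for the median of 12 genes that rose in knockout-labelled culture and were low in control-labelled tumors, since in the knockout-labelled tumors that median fell short of the level set by epithelial genes by log2 gaps of -2.73, -2.16 and -1.41, as for Apob at 32.6 CPM in knockout-labelled cultures and 0.314 CPM in knockout-labelled tumors, although 1, 5 and 6 of the 12 lay above every control-labelled tumor, Cyp2c55 (5.78 against 1.01 CPM on average), Tet1 (2.20 against 0.514) and Bst1 (39.3 against 19.9) being higher. For the whole set dilution stays open, because host cells may express many of these genes, whose gap to epithelial genes reached 2.08. Also open is that the knockout-labelled tumors grew from cells without the chromosome-wide shifts. Slopes of those tumors on the culture shifts were 0.296, 0.241 and 0.094, against 0.043, -0.272 and 0.223 in control-labelled tumors. The 2 sets overlapped. Each control-labelled tumor was set against the mean of the other control-labelled tumors, which widens those slopes. The first 3 windows of chromosome 1 stood at -0.49, -0.43 and -0.55 in culture and at -0.38, -0.30 and -0.47 in tumors. The median gene of chromosome 6 stood at -0.45 in culture and -0.06 in tumors, so the shifts were not seen alike there.

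Pogz RNA was higher in the cultures labelled knockout, by 0.45 ± 0.04 on the log2 scale. Normalization as the whole cause is argued against, since the lowest log2 fold change less 2 SE over 3 normalizations was 0.36, and so are 1 or 2 mislabelled libraries, since the lowest knockout-labelled culture was 1.30-fold over the highest control-labelled culture. A shift shared by the genes of chromosome 3 is a candidate explanation, as Pogz lay at the 70.9th percentile of 509 chromosome 3 genes and at 0.12 ± 0.04 once their median was taken out. Exchanged labels of all 6 cultures stay open, which would read the fold as 0.733, because the files hold no other mark of the edited line. Such a shift of whole chromosomes may reflect a difference in chromosome copies between the lines, which was not tested, since no DNA was sequenced.

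Milk and B cell lists were placed higher in the knockout-labelled tumors at the preset correlation only (adjusted p = 0.725 for both with an estimated correlation), with medians of 2.304 and 4.09 on the log2 scale, and the B cell score was 1.153, 2.793 and 6.937 in tumors POGZ_KO_8454, POGZ_KO_8455 and POGZ_KO_8459 against 2.235 in tumor POGZ_VC_8447. A larger share of host RNA, which raises the markers of all host cells alike, is argued against as the whole cause, since the medians of milk and neutrophil genes lay at least 2.05 apart with each tumor left out. Neutrophil genes were the only comparison made. Lists of fibroblasts, endothelial cells, adipocytes, T and NK cells and macrophages were also placed higher at the preset correlation, so host share as part of the cause stays open. Deeper knockout-labelled libraries are argued against, since thinning all tumors to the smallest total kept at least 0.971 of the medians. Lymph node tissue in tumor POGZ_KO_8459 stays open, since 4 of 7 lymph node genes were highest in that tumor but the median of the 7 was 1.12-fold over the highest other tumor, with Ccl21a at 2.955 CPM, while Cxcl13 was at 9.36 CPM there and at 19.1 CPM in tumor POGZ_KO_8455. Mammary tissue of the host in the resected piece may also contribute and was not tested.

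Among the 10 splits of 6 samples the share cannot go below 0.1, so a count that no other split reaches still cannot exclude chance. The count of genes in culture was 7523 for the real split, as many in 1 split, with 0 as the highest of the others. The count of lists was 9, as many in 1 split, with 8 as the highest other and 5 as the median of the others. In tumors the counts were 0 genes, as many in 10 splits, with 10 as the highest other, and 20 lists, as many in 4 splits, with 26 as the highest other. The other tumor splits called a median of 17 lists. Camera at the preset correlation thus called about as many lists with the labels mixed as with the real labels. Control-labelled tumors against cultures gave 11172 genes, as many in 1 split, with 0 as the highest other.

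Of 100 draws of the labels for the difference between systems, 7 gave as many as 377 genes, and the highest other gave 1168. All 7 kept the real culture groups, as 9 of the 100 draws did, and with them the culture effect, while the highest count with the culture groups mixed was 8. The draws therefore do not judge chance for this count, which rests on the structure of the cultures. An absolute correlation of 0.07 or more between the systems came in 58 of 100 pairs of splits, the highest other being 0.22, so chance cannot be excluded for it. The overlap was 0, which all 100 pairs reach, with 2 as the highest other, so it was no test of chance.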

How the results depend on the processing

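The alternatives that left out structural RNA genes, thinned the tumors, left out tumor POGZ_VC_8451 and tumor POGZ_KO_8459, used Xist or took out chromosome medians were chosen after the data were seen. The count of 7523 in culture stayed within 1.5 times under other scalings, filters, DESeq2 (6221), limma-voom (7492), the block by number (7237) and each library left out (6551 to 7407). It was 1501 with all 12 samples in 1 fit, whose spread is that of the tumors too, and 3085 against a fold change of 1.2, a stricter test. The count in tumors was 0 throughout except for DESeq2 (66) and 1 fit of all samples (64). That fit gives the tumors a spread shared with the cultures, a biological coefficient of variation of 20.1% against 28.6% for tumors alone. The cause for DESeq2 was not tested. The difference gave 953 genes with DESeq2, the cause of which was not tested, 232 and 125 under stricter tests (a fold change of 1.2, an adjusted p of 0.01), 313 without tumors POGZ_VC_8451 and POGZ_KO_8459 and 147 to 1588 with a library left out. Control-labelled tumors against cultures gave 8870 to 12866. Pogz in culture stayed at 0.43 to 0.47 with a library left out and was 0.45 with the block by number, but with 1 fit of all samples it was 0.44 and past no threshold (edgeR, Benjamini-Hochberg adjusted p = 0.098; range 2.93e-14 to 0.098). Pogz in tumors ran from -0.068 to 0.25 with a tumor left out, was 0.33 without tumors POGZ_VC_8451 and POGZ_KO_8459 and 0.34 with Xist as a covariate, with -0.005 without tumor POGZ_VC_8447 and -0.068 without tumor POGZ_KO_8454.

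Lists in culture numbered 0 with the correlation estimated from the data, 21 with fry, 10 with the block by number and 8 to 9 with a library left out. In tumors they numbered 0 with the correlation estimated from the data, 0 with fry, 13 to 23 with a tumor left out, 13 without tumors POGZ_VC_8451 and POGZ_KO_8459 (10 higher and 3 lower), and 13 with Xist as a covariate (6 higher and 7 lower), which moved mitosis genes from higher to lower. The correlation between systems was 0.06 to 0.10 under other settings and -0.005 to 0.14 with a library left out, and the overlap was 20 genes with DESeq2.

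Over 82 named values in culture, 50 alternatives ended a call, most of them in 1 fit of all samples, and 1176 left the sign and the call, or for Smad7 its absence, as they were. For the 10 genes with the smallest p of the difference, all 190 alternatives kept the call, and the other genes named for it were not run. Of 37 named values in tumors, 14 alternatives gave a call with DESeq2 or 1 fit of all samples and 14 turned the sign of a value that no setting called. With each tumor left out, Tgfb2 ran from -0.058 to 0.32, Tgfb3 from -0.93 to 0.11, Tgfbr1 from -0.13 to 0.28, Ccn2 from -0.44 to 0.22, Cdh1 from -0.35 to 0.030, Id2 from -0.23 to 0.23, S100a9 in tumor libraries from -1.42 to 0.27 and Zfhx4 from -0.20 to 0.18. The sign turned without POGZ_KO_8454 for Tgfbr1, Ccn2, Cdh1, Id2 and S100a9, without POGZ_KO_8455 for Tgfb2 and Zfhx4, without POGZ_KO_8459 for S100a9, without POGZ_VC_8447 for Tgfb3, without POGZ_VC_8448 for S100a9 and Zfhx4, and without POGZ_VC_8451 for Ccn2 and Id2. With no filter Id2 was at 0.0045. Tumor depth and spread left 2-fold changes mostly out of reach, as 13.7% were called in simulation.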

Other observations

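The values below were chosen after the data were seen, and no further tests were run on them.

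Kctd12b (X chromosome, from 153685154) and Ubqln2 (X chromosome, from 153498227) rose in culture, from 0.490 ± 0.152 to 9.44 ± 0.515 CPM and from 1.55 ± 0.290 to 29.2 ± 1.87 CPM (SD, n = 3). On the same chromosome Dmd, dystrophin, fell from 17.6 ± 0.399 to 0.146 ± 0.0823 CPM and Armcx4 from 14.3 ± 0.441 to 0.255 ± 0.0745 CPM.

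Control-labelled tumors POGZ_VC_8447, POGZ_VC_8448 and POGZ_VC_8451 had Sema3c at 3.18, 0.240 and 0.664 CPM, far from the 122 to 125 CPM of control-labelled cultures, although they are labelled as tumors of the same line. Marcks was at 127, 101 and 123 CPM in those tumors and at 137, 150 and 196 CPM in tumors POGZ_KO_8454, POGZ_KO_8455 and POGZ_KO_8459.

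In tumors the median gene of chromosome 18 was 0.24 higher, at 0.18, 0.26 and 0.24 in tumors POGZ_KO_8454, POGZ_KO_8455 and POGZ_KO_8459 and -0.10 to 0.08 in control-labelled tumors, and that of chromosome 8 stood at -0.16. Genes of the X chromosome were at -0.56 in tumor POGZ_VC_8451 and at 0.26 and 0.32 in tumors POGZ_VC_8447 and POGZ_VC_8448. For both chromosomes each control-labelled tumor was compared with the mean of the other control-labelled tumors, which widens its value. The share of ribosomal RNA in the counts was 5.33% in tumor POGZ_VC_8451 and 1.55% to 2.54% in the other tumors.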
